A study of Mus musculus with 8 samples.

How the data were processed

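The series holds 8 RNA sequencing libraries from C57BL/6 mouse bone marrow cells, 4 labelled ex vivo CLP and 4 labelled cCLP. Per the labels, RNA was extracted from sorted cells with TRIzol, 100 ng of total RNA went into TruSeq stranded libraries after Ribo-Zero depletion of ribosomal RNA, and paired reads of 75 nt were sequenced on a NextSeq500. Per the labels, the authors used TopHat2, Bowtie2 and HTSeq 1.0.6 with the GRCm38 (mm10) genome. The role of each tool, the strand setting, the annotation release and any later scaling are not stated.

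The deposited value of each gene is a score, a whole number per Ensembl gene ID on a scale that no label names. The design fixed before the data were examined assumed counts, and the unit was first recorded as counts and then corrected. For genes with mean values from 5 to 50, the dispersion index between ex vivo CLP 3 and 4 averaged 0.541 over 6876 genes, where simulated Poisson counts gave 1.03, and between cCLP 3 and 4 it averaged 0.260 over 6768 genes, where simulated counts gave 1.00. The median value also fell with gene length, from 23.8 and 16.2 to 13.0 and 10.6 over 4 equal bins. Read counts cannot vary less than their sampling error, so the score was not treated as a count. Depth is therefore unknown, no counting interval or detection limit can be given, and a gene without signal is said to be listed at 0. The sums of values ranged from 378594 to 704305 per library and are not depths. For the same reason edgeR, DESeq2 and limma-voom, which need counts and were planned, were not used.

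Each library listed 39179 gene IDs. Of these, 37693 matched the GENCODE vM21 annotation, which gave symbols, positions and biotypes. IDs without a match held 0.31% of the summed values, and protein-coding genes held 97.0%. A total of 0 pairs of libraries were identical.

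Groups were taken from the labels. Library factors were trimmed means of log ratios against a reference library (30% of ratios and 5% of levels trimmed). A gene was tested when its scaled value was at least 10 in at least as many libraries as the smaller group holds. Linear models of log2(scaled value + 1) on group were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p below 0.05 was called. A log2 fold change is cCLP minus ex vivo CLP. Intervals are 95% confidence intervals of the fold change from the same fit. Tables were computed with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.

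The main comparison used all 8 libraries as labelled. A comparison of ex vivo CLP 1, 3 and 4 with cCLP 2, 3 and 4 was added after the data had been seen, because the libraries labelled ex vivo CLP replicate 2 and cCLP replicate 1 lay with the other group. No library was moved to another group.

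The 28 gene lists were fixed before the data were examined, from general knowledge of lymphoid progenitors, cell types that the gate or culture could admit, the cell cycle, signalling, stress and metabolism. They were tested with camera in limma at a preset correlation of 0.01 when at least 3 members were tested, and again with an estimated correlation and with fry. For each list the called members were counted over all genes tested and adjusted over the list alone. Cell type lists share members with the progenitors studied, for example Kit, Ly6a, Irf8, Rag1, Dntt and Mpo, which CLPs or their close relatives also express.

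Genes were named by a rule fixed before the data were examined. Part a took 23 sort gate genes and regulators, of which 16 were tested. Part b took the 8 largest changes up and the 8 largest down among called genes with a mean log2 relative value (library sum 1000000) of at least 5 and groups that did not overlap. Part c took the called member of each list with the largest change up and the one with the largest change down. Parts b and c named 0 genes over the 8 libraries, and 16 and 39 over the 6 libraries, giving 69 genes in all. The other list members named (Cd24a among them), and Hmga2, the neutrophil and granule genes, the MHC genes and the remaining Hoxa genes, were chosen after their values were seen.

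Shares of the summed values were compared by exact two-sided permutation tests, adjusted over 7 shares. Whether the replicate numbers pair the libraries is unknown. After removal of the means of the labelled groups, the correlation across genes between libraries of the same number was 0.595, 0.843, -0.575 and -0.86, but these means include the libraries labelled ex vivo CLP 2 and cCLP 1, which lie with the other group, so the values cannot show whether the numbers pair libraries.

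Alternatives fixed before the data were examined were other scalings (relative log expression, upper quartile, total), other filters on low values (none, or a relative value of 1 per 1000000 in every library of a group), genes without abundant RNA classes, protein-coding genes only, offsets for GC content and gene length, a replicate block, each library left out in turn, and the other set tests. Quantile normalization, a filter of 5, an added value of 0.5 or 5, limma without trend or robust estimation, and the 6 libraries with all of their alternatives were added after the data had been seen. On simulated data with 100 genes changed by a log2 size of 1 and 100 by 2, the 8-library fit recovered 73% and 94% with 5 false calls (2.9% of calls), and the 6-library fit recovered 91% and 99% with 12 false calls (5.9% of calls). Each simulated library lay with its labelled group, and the changes were put on randomly picked genes. The real libraries labelled ex vivo CLP 2 and cCLP 1 lay with the other group. The 8-library recovery therefore does not describe the power of the real 8-library comparison.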

Results

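Gene expression was measured by stranded total RNA sequencing in mouse common lymphoid progenitors (CLPs), bone marrow cells that give rise to B, T, natural killer and other lymphoid cells. The libraries formed 2 groups of 4. The ex vivo CLP group came from cells sorted fresh from C57BL/6 bone marrow. The cCLP group came from cells kept in culture for 2 months with Flt3 ligand and a low dose of IL-7 on OP9, a mouse stromal cell line, and then sorted. Both sorts took lineage-negative cells that carried Flk2 (the product of Flt3), the IL-7 receptor and CD27 and lacked Ly6d. No label gave an animal, a culture or a sequencing batch, so every p-value measures only the spread between these libraries. The deposited values were whole numbers per gene that were not raw counts, so the sequencing depth behind them is unknown. They summed to 378594, 452321, 439325 and 704305 in ex vivo CLP 1 to 4 and to 505499, 434009, 527091 and 604733 in cCLP 1 to 4, with between 11371 and 12779 genes above 0 per library. Below, gene values are scaled values (deposited values divided by a library factor), and positions are on GRCm38.

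The first question was how the 8 libraries related to each other. The library labelled ex vivo CLP replicate 2 was closest to cCLP 2, 3 and 4, with Spearman's rho of 0.977, 0.973 and 0.979 across genes, against 0.913 to 0.927 with the other ex vivo CLP libraries. The library labelled cCLP replicate 1 was closest to ex vivo CLP 1, 3 and 4, with rho of 0.974, 0.970 and 0.974, against 0.924 to 0.925 with the other cCLP libraries. Genes are not independent replicates, so these values describe likeness and carry no test. Single genes showed the same arrangement. Igf2bp3, which encodes a fetal-type RNA-binding protein, was listed at 0 in ex vivo CLP 1, 3 and 4 and in cCLP 1. It was listed at 74 in ex vivo CLP 2 and at 83, 103 and 106 in cCLP 2 to 4. Ctsg, which encodes the granule protease cathepsin G, was listed at 141, 458 and 660 in ex vivo CLP 1, 3 and 4, at 354 in cCLP 1, and at 0 in ex vivo CLP 2 and cCLP 2 to 4. Rag1, which encodes a subunit of the antigen receptor recombinase, was listed at 353 in ex vivo CLP 2 and at 3 in cCLP 1. Its values were 7, 1 and 2 in ex vivo CLP 1, 3 and 4 and 276, 281 and 391 in cCLP 2 to 4. On an axis running from 0 at the mean of ex vivo CLP 1, 3 and 4 to 1 at the mean of cCLP 2 to 4, ex vivo CLP 2 lay at 1.01 and cCLP 1 at 0.035.

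**Figure D1:**
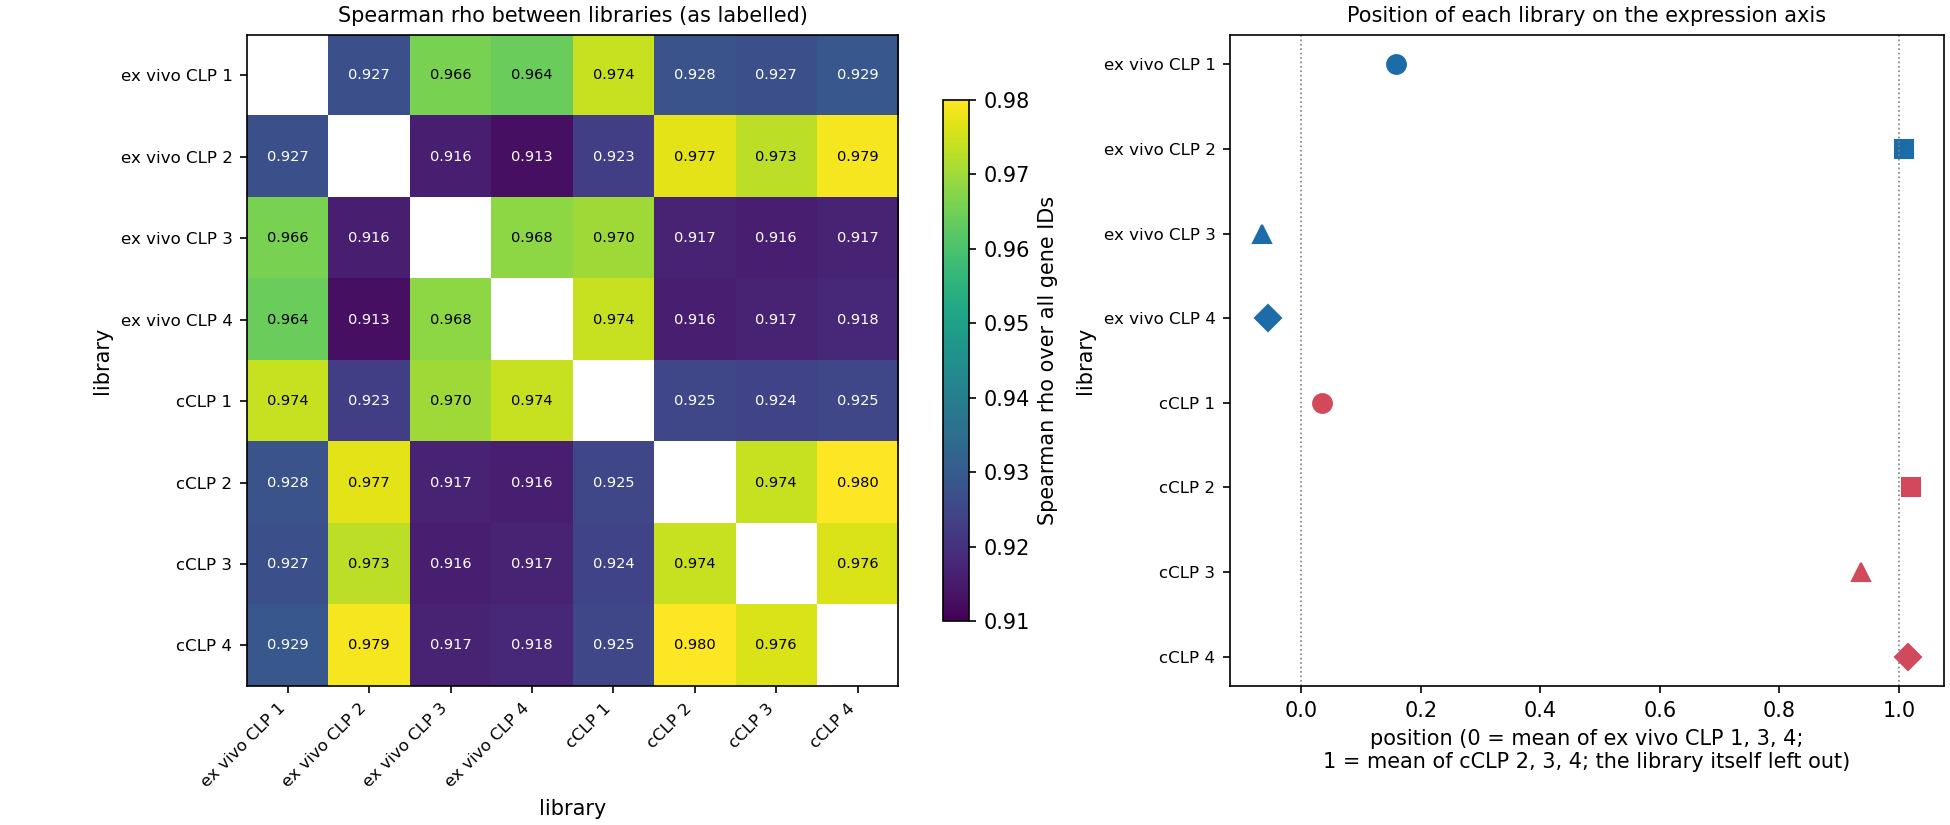
Left, Spearman's rho between each pair of the 8 libraries over all gene IDs. Right, each library's position on an axis from the mean of ex vivo CLP 1, 3 and 4 (position 0) to the mean of cCLP 2, 3 and 4 (position 1), with ex vivo CLP in blue, cCLP in red and the marker shape giving the replicate number; the library labelled ex vivo CLP 2 lies at 1.01 and the library labelled cCLP 1 at 0.035.

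The second question was which genes differed between ex vivo CLPs and cCLPs over all 8 libraries as labelled. In this comparison Rag1 averaged 100.4 ± 193 (SD, n = 4) in ex vivo CLPs and 224 ± 149.5 in cCLPs, a log2 fold change of 3.07 ± 2.02 (SE) with adjusted p = 0.484. Il7r, which encodes the IL-7 receptor alpha chain used in the sort, averaged 80.7 ± 92.5 and 166 ± 93.7, a log2 fold change of 1.40 ± 0.98 with adjusted p = 0.488. For the other sort genes the log2 fold changes were 0.15 ± 0.13 (SE, n = 4) for Flt3, 0.04 ± 0.17 for Cd27 and -1.97 ± 1.35 for Ly6d, and the sign for Cd27 turned without ex vivo CLP 2 (-0.07) or cCLP 1 (-0.06). With 1 library left out Rag1 ranged from 2.27 to 4.75, Il7r from 0.93 to 2.13 and Ly6d from -3.25 to -1.53. Of 6486 genes tested with limma, 0 were higher and 0 lower in cCLPs, 477 had an unadjusted p below 0.05 against 324 expected by chance, and the smallest adjusted p was 0.484. The gene with the smallest unadjusted p among those named here was Egr1, an immediate early gene, which averaged 15.4 ± 3.86 and 29.5 ± 5.31 (log2 fold change 0.91 ± 0.19, adjusted p = 0.484). It was also called when p-values were adjusted over the list alone, as the only such member of the immediate early list. In the B lineage list, Cd24a fell on the same basis, from 339 ± 40.1 to 205 ± 59.5 (log2 fold change -0.76 ± 0.21, adjusted p = 0.484 over all genes). For 5280 genes (81.4%) the 95% confidence interval of the fold change lay inside 2-fold. Each labelled group held 1 library that lay with the other group, which brings the log2 fold changes nearer to 0 and widens their intervals. For Rag1 the log2 fold change was 3.07 here and 6.32 without these libraries. The share inside 2-fold is therefore no plain measure of how alike ex vivo CLPs and cCLPs are. With the libraries labelled ex vivo CLP replicate 2 and cCLP replicate 1 left out, 1369 genes were higher and 1459 lower.

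Of the 28 gene lists, 24 had at least 3 tested members over the 8 libraries, and the camera set test called 1 list higher and 5 lower in cCLPs. Cholesterol synthesis was higher (median log2 fold change 0.76, adjusted p = 4.7e-05). G2 and M phase (-0.31, adjusted p = 3.95e-06), S phase (-0.31, adjusted p = 0.000178), myeloid genes (-2.99, adjusted p = 0.00265), oxidative phosphorylation (-0.085, adjusted p = 0.0157) and the unfolded protein response (-0.28, adjusted p = 0.0421) were lower. None of these 6 calls held with an estimated correlation (adjusted p = 0.865 for each), and fry, a test of each list by itself, called 0 lists. The calls moved with single libraries. The number of lists lower was 3 without ex vivo CLP 3, 3 without cCLP 2, 8 without ex vivo CLP 2 and 9 without cCLP 1. The number higher was 2 without ex vivo CLP 2, 2 without ex vivo CLP 3 and 3 without cCLP 1.

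The libraries of the 2 groups did not differ detectably in composition. Mitochondrially encoded genes took 9.13% ± 1.47 (SD, n = 4) of the summed values in ex vivo CLPs and 10.01% ± 1.75 in cCLPs (exact two-sided permutation p = 0.457, adjusted p = 0.857). Cytosolic ribosomal protein genes took 21.6% ± 1.254 and 21.9% ± 1.47 (exact permutation p = 0.743), and the 20 most abundant genes 19.2% ± 1.72 and 19.7% ± 1.82 (exact permutation p = 0.657). Replication-dependent histones took 0.082% ± 0.027 and 0.086% ± 0.015, Malat1 0.015% ± 0.006 and 0.014% ± 0.004, haemoglobin genes 0.004% ± 0.003 and 0.002% ± 0.001, and the stromal list 0.010% ± 0.005 and 0.006% ± 0.006. The adjusted p was 0.857 for each of the 7 shares, and 4 libraries against 4 allow no exact p below 0.0286. The difference for mitochondrially encoded genes, 0.879 percentage points, was 0.28 without cCLP 4 and 1.659 without cCLP 1. Without ex vivo CLP 1 the difference between the groups turned to -0.054 percentage points for ribosomal protein genes, -0.01 for histones and -0.083 for the 20 most abundant genes. It turned to -0.292 for ribosomal protein genes without cCLP 3, and to -0.143 for the 20 most abundant genes and -0.00056 for histones without cCLP 4.

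The third question was what separated ex vivo CLP 1, 3 and 4 from cCLP 2, 3 and 4. These 6 libraries were chosen after the data had been seen, from where the profiles lie, so their p-values hold only given that choice. Compared with ex vivo CLP 1, 3 and 4, cCLP 2 to 4 had more Rag1, Rag2, Il7r and Ccr9 RNA, more of the fetal-type genes Igf2bp3 and Hmga2 and more of most cholesterol synthesis enzymes. They had less RNA of most tested myeloid, dendritic, interferon response and immediate early genes, less Dntt, and less of many cell cycle genes, although none of the list calls held with an estimated correlation. A gene below 10 in every library of a group passed the filter on low values only through the other group, which fixed its direction. Counts and set tests of lists that hold such genes are limited by this. Of 6573 genes tested, 1369 were higher and 1459 lower in cCLP 2 to 4, of which 323 and 481 changed at least 2-fold. For 5117 genes (77.8%) the 95% interval lay inside 2-fold. The groups did not overlap for 3664 genes (chance gives 10%), which is no independent evidence, as the libraries were chosen from where the profiles lie. Without cCLP 4 the number of genes higher was 889, and without a filter on low values the numbers were 2215 higher and 2761 lower, of which 700 and 1496 at least 2-fold.

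Genes of the sort gate did not move as a block. Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176) rose from 36.9 ± 33.5 (SD, n = 3) in ex vivo CLP 1, 3 and 4 to 215 ± 14.9 in cCLP 2 to 4, a log2 fold change of 2.86 ± 0.52 (SE) with adjusted p = 0.00457. Flt3 was at 229 ± 28.9 and 279 ± 5.85 (0.29 ± 0.12, adjusted p = 0.081). It passed the threshold without ex vivo CLP 1 (adjusted p = 0.0173) and with offsets for GC content and gene length (adjusted p = 0.0333). Cd27 was at 87.6 ± 15.7 and 77.1 ± 6.42 (-0.17 ± 0.14, adjusted p = 0.354), and its sign turned to 0.08 with those offsets. Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620), whose product was sorted against, fell from 33.2 ± 2.73 to 0.963 ± 0.103 (-4.12 ± 0.14, adjusted p = 4.95e-07). The progenitor receptor gene Kit fell from 29.7 ± 5.49 to 10.2 ± 0.705 (-1.44 ± 0.15, adjusted p = 0.000128), and Ly6a, which encodes Sca-1, fell from 29.9 ± 3.09 to 0.323 ± 0.560 (-4.62 ± 0.28, adjusted p = 6.03e-06). For Ly6d, Ly6a and other genes near 0 in a group, the added 1 makes the fold change smaller than the ratio of the printed means. Ly6d was listed at 1 in each of cCLP 2 to 4, so its SD of 0.103 there reflects only the library factors. The same holds for Nfil3, Cd74 and Socs3 below. For these genes the SE and p-value take no spread in expression from cCLP 2 to 4. In the sort gate list, which also holds Kit and Ly6a from outside the stated gate, 1 of 6 tested members rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.140).

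Recombinase genes and the gene for terminal transferase moved in opposite directions. Rag1 (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501) rose from 3.79 ± 4.22 (SD, n = 3) to 300.3 ± 31.9, a log2 fold change of 6.32 ± 0.52 (SE) with adjusted p = 0.0001. Its neighbour Rag2 rose from 9.90 ± 9.67 to 80.8 ± 7.25 (3.26 ± 0.53, adjusted p = 0.00274). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), which encodes terminal transferase, fell from 1428 ± 778 to 153 ± 92.0 (-3.25 ± 0.48, adjusted p = 0.00157), and Cd79b, which encodes a B cell receptor signalling chain, fell from 36.2 ± 4.17 to 2.14 ± 1.20 (-3.63 ± 0.26, adjusted p = 1.94e-05). In the B lineage list 3 of 7 tested members rose (Rag1, Rag2 and Cd72) and 3 fell (Dntt, Cd79b and Cd24a), with the same counts adjusted over the list alone and camera adjusted p = 0.916. Its median log2 fold change was near 0 and changed sign with the scaling (-0.48 to 0.03), while its mean was 0.51. The B lineage regulators were too low to test: Ebf1 was listed at 1, 0 and 0 in ex vivo CLP 1, 3 and 4 and at 7, 6 and 9 in cCLP 2 to 4, and Pax5 at 0 in those ex vivo libraries and at 1, 1 and 2. Cd79a, of the same list, was also not tested and went the other way from Cd79b. It was listed at 1 in each of ex vivo CLP 1, 3 and 4 and at 7, 7 and 16 in cCLP 2 to 4. Ighm was the tested member of the antigen receptor list and was not called.

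Genes of the T, natural killer and innate lymphoid programmes were few. Bcl11b was listed at 0 in all 8 libraries, Gata3 at no more than 1, Zbtb16 at no more than 1 and Tcf7 at no more than 4, so none was tested. Notch1 was at 19.6 ± 3.26 (SD, n = 3) and 22.9 ± 5.07 (log2 fold change 0.21 ± 0.17 SE, adjusted p = 0.376). In the T lineage list 0 of 4 tested members rose and 2 fell (Cd7 and Lat), the same adjusted over the list alone (camera adjusted p = 0.117). Cd7 was listed at 11, 16 and 27 in ex vivo CLP 1, 3 and 4 and at 0 in cCLP 2 to 4. In the natural killer and innate lymphoid list 3 of 7 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.984), with a median of 0.49 and a mean of -0.84. Il18r1, an IL-18 receptor gene, rose from 6.84 ± 3.73 to 47.2 ± 3.93 (2.71 ± 0.28, adjusted p = 0.000201), and Nfil3, which encodes a transcription factor, fell from 37.5 ± 8.56 to 0.963 ± 0.103 (-4.27 ± 0.19, adjusted p = 1.15e-06). Id2 was at 36.7 ± 9.40 and 50.9 ± 6.00 (0.49 ± 0.19, adjusted p = 0.0716). It passed the threshold without ex vivo CLP 3 (adjusted p = 0.0386) and under 3 other settings.

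Most tested myeloid and dendritic genes fell. In the myeloid list 2 of 17 tested members rose and 15 fell, the same adjusted over the list alone (camera adjusted p = 7.36e-09; adjusted p = 0.387 with an estimated correlation). In cCLP 2 to 4, 9 of the 17 were listed at 0 in every library: Elane, Csf1r, Csf3r, Ngp, Ltf, Camp, Ctsg, S100a8 and S100a9. These 9 passed the filter on low values only through ex vivo CLP 1, 3 and 4, so they could only fall. The same holds for Prtn3, Lyz2 and Cebpa, which were below 10 in each of cCLP 2 to 4. Of the members that fell, Mpo and Spi1 were above 10 in both groups. Neither the count nor the set test is therefore evidence that the list as a whole fell. Lyz2, which encodes lysozyme, fell from 179.5 ± 32.5 (SD, n = 3) to 8.21 ± 1.69 (log2 fold change -4.29 ± 0.17 SE, adjusted p = 8.6e-07). Cebpa, a myeloid transcription factor gene, fell from 22.5 ± 8.84 to 1.29 ± 0.575 (-3.31 ± 0.32, adjusted p = 0.000115). Spi1, which encodes PU.1, fell from 67.3 ± 19.9 to 37.7 ± 3.22 (-0.78 ± 0.22, adjusted p = 0.0211), a call that ended without ex vivo CLP 3 (adjusted p = 0.066), ex vivo CLP 4 (0.0766), cCLP 2 (0.0817) or cCLP 4 (0.0544). Fcer1g and Fcgr3 rose, and Fcgr3, an Fc receptor gene, went from 11.96 ± 9.65 to 90.6 ± 8.04 (3.34 ± 0.77, adjusted p = 0.0121; adjusted p = 0.0522 without cCLP 2). In the dendritic cell list 4 of 15 rose (Ptprs, Ccr9, Cox6a2 and Sirpa) and 10 fell, the same adjusted over the list alone (median -2.02, camera adjusted p = 0.00369; adjusted p = 0.387 with an estimated correlation). Irf8 (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694), a regulator of dendritic and monocyte development, fell from 158 ± 22.4 to 5.46 ± 1.26 (-4.63 ± 0.16, adjusted p = 5.7e-07). Cd74, the MHC class II invariant chain gene, fell from 60.7 ± 8.65 to 0.963 ± 0.103 (-4.97 ± 0.14, adjusted p = 2.16e-07). Irf8, Cd74, H2-Aa and H2-Ab1 were below 10 in each of cCLP 2 to 4, and Ccr9 in each of ex vivo CLP 1, 3 and 4. The filter fixed the direction of these genes. For the dendritic cell list, too, neither the count nor the set test is evidence that the list as a whole fell.

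The 3 tested fetal-type genes rose, while stem and multipotent progenitor genes went both ways. In the stem and multipotent progenitor list 2 of 11 tested members rose (Hoxa10 and Hoxa7) and 6 fell (Kit, Cd34, Mycl, Lmo2, Erg and Ly6a), against 3 and 6 adjusted over the list alone (median -1.20, camera adjusted p = 0.0931). Hoxa10 rose from 2.64 ± 0.259 (SD, n = 3) to 59.9 ± 6.39 (log2 fold change 4.06 ± 0.12 SE, adjusted p = 2.16e-07). All 3 tested members of the fetal-type list rose (Igf2bp3, Hmga2 and Arid3a), also adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.330 with an estimated correlation). All 3 were below a scaled value of 10 in ex vivo CLP 1, 3 and 4 and passed the filter on low values only through cCLP 2 to 4. The filter therefore fixed their direction, and neither the count nor the set test is evidence that the list as a whole rose. Hmga2, a chromatin protein gene chosen for its values after they were seen, was at 3.04 ± 1.85 and 62.9 ± 7.23 (4.09 ± 0.31, adjusted p = 3.79e-05). Other genes of that list, Lin28b, Lin28a, Igf2bp1, Igf2 and H19, were listed at 0 in all 8 libraries. Car2 was the tested erythroid and megakaryocyte member and fell from 109.9 ± 29.5 to 9.63 ± 4.48 (-3.43 ± 0.31, adjusted p = 9.68e-05). Serpinf1 was the tested member of the stromal list and fell from 32.4 ± 8.75 to 0.609 ± 0.530 (-4.40 ± 0.31, adjusted p = 1.78e-05), and the stromal genes Col1a1, Col1a2, Col3a1, Sparc, Bgn and Dcn were listed at 0 in all 8 libraries.

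**Figure D2:**
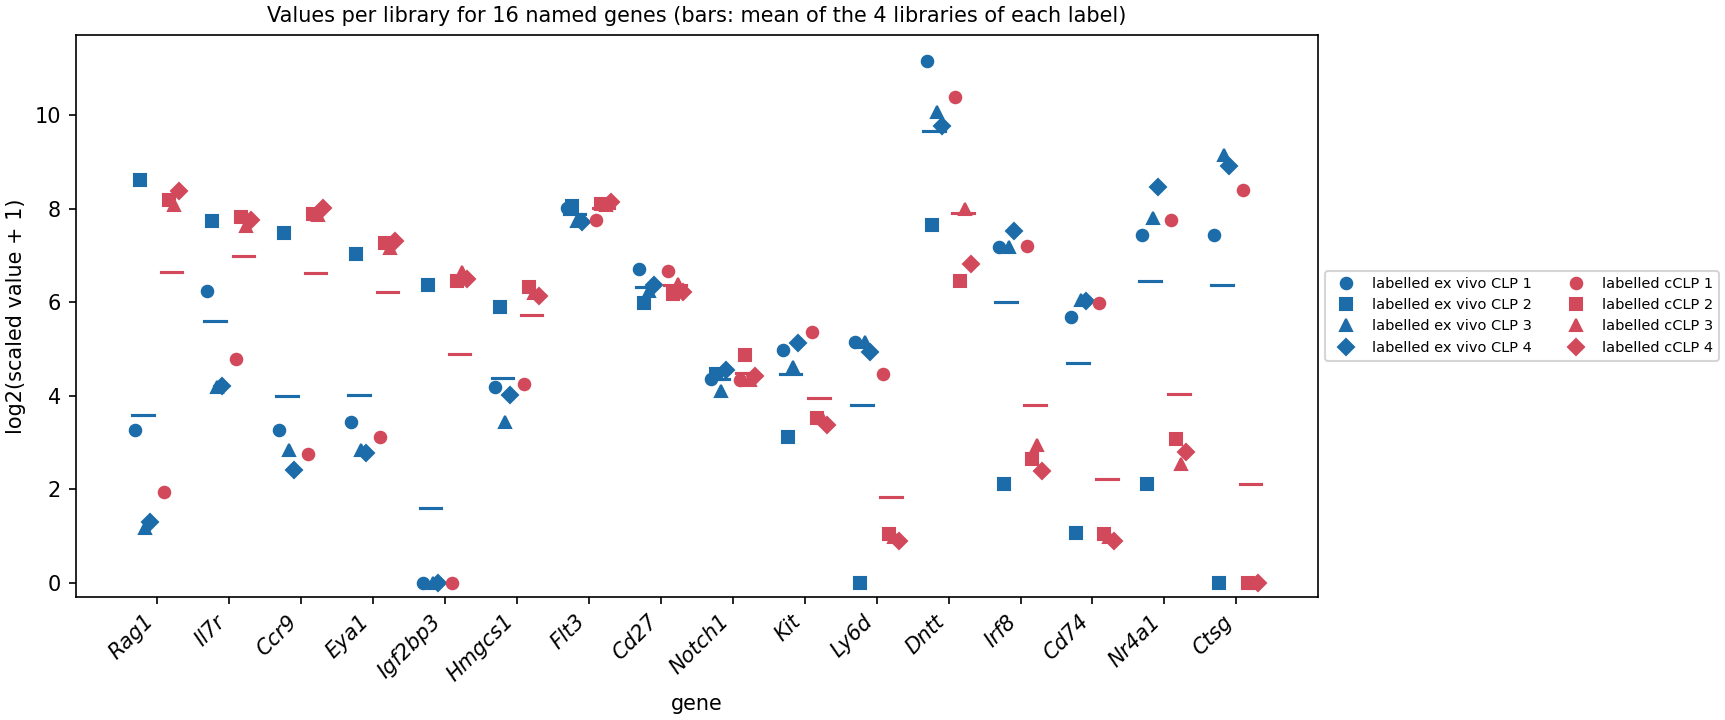
log2 of the scaled value plus 1 for 16 genes in each of the 8 libraries, with ex vivo CLP in blue, cCLP in red, the marker shape giving the replicate number and bars at the mean of the 4 libraries of each label. In Rag1, Igf2bp3, Irf8 and Ctsg the library labelled ex vivo CLP 2 sits with cCLP 2 to 4 and the library labelled cCLP 1 with ex vivo CLP 1, 3 and 4.

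Of the genes with the largest changes at a mean log2 relative value (library sum 1000000) of at least 5, the 8 that rose were Rag1, Ccr9, Gfra1, AB124611, Eya1, Mt1, Tnni1 and Pde3b, with log2 fold changes from 3.53 to 6.32. Ccr9 (ENSMUSG00000029530, chromosome 9, 123678439 to 123784330), a chemokine receptor gene used in homing to the thymus and gut, rose from 6.43 ± 2.14 (SD, n = 3) to 245 ± 15.4 (5.09 ± 0.19 SE, adjusted p = 7.27e-07). Eya1, a transcriptional cofactor gene, rose from 7.34 ± 2.23 to 152 ± 7.19 (4.23 ± 0.17, adjusted p = 8.6e-07). Those that fell included Ccl4, Nr4a1, Ctla2a, Irf8, Ifitm2, Lyz2 and Tmem176a, with log2 fold changes from -5.44 to -4.26. Ccl4, a chemokine gene, fell from 300.8 ± 60.0 to 6.11 ± 2.33 (-5.44 ± 0.24, adjusted p = 1.54e-06). In the homing and adhesion list 4 of 14 tested members rose (Ccr9, Itgb2, Itga4 and Itga6) and 6 fell (Itgb7, Cd44 and Cxcr4 among them), against 4 and 7 adjusted over the list alone (median -0.41, camera adjusted p = 0.177).

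Most tested cell cycle genes and cell cycle brakes fell. In S phase genes 0 of 25 tested members rose and 18 fell (0 and 19 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 8.52e-06; adjusted p = 0.0982 with an estimated correlation). In G2 and M phase genes 0 of 26 rose and 19 fell (0 and 20 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 2.96e-05; adjusted p = 0.406 with an estimated correlation). Mki67, the gene of the proliferation marker Ki-67, fell from 112 ± 19.2 (SD, n = 3) to 66.2 ± 5.05 (log2 fold change -0.74 ± 0.14 SE, adjusted p = 0.0031). Gins1, a replication helicase subunit gene, fell from 43.0 ± 8.18 to 18.7 ± 1.68 (-1.14 ± 0.14, adjusted p = 0.000433), and Ccna2, which encodes cyclin A2, from 110.0 ± 8.54 to 59.1 ± 7.93 (-0.89 ± 0.12, adjusted p = 0.00076). Of the brakes 0 of 8 rose and 6 fell (Btg1, Btg2, Cdkn1a, Cdkn1b, Cdkn2c and Cdkn2d), the same adjusted over the list alone (median -1.19, camera adjusted p = 0.00485; adjusted p = 0.387 with an estimated correlation). Btg1, an antiproliferative gene, fell from 93.1 ± 25.7 to 13.8 ± 1.86 (-2.64 ± 0.19, adjusted p = 2.25e-05). Cdkn2a was listed at no more than 3 in any library and was not tested. Of the p53 targets 6 of 12 rose and 3 fell, the same adjusted over the list alone, with a median of 0.38, a mean of -0.27 and camera adjusted p = 0.486. Sesn1 rose from 43.6 ± 17.0 to 124 ± 3.97 (1.55 ± 0.23, adjusted p = 0.00116), and Plk2 fell from 77.4 ± 12.2 to 0.609 ± 0.530 (-5.66 ± 0.26, adjusted p = 1.66e-06).

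Cytokine, interferon and stress genes fell more often than they rose. In the IL-7 and STAT5 list 3 of 16 tested members rose (Il7r, Il2rg and Socs2) and 8 fell (Stat5a, Pim1, Bcl2l11, Ccnd3, Mcl1, Socs3, Bcl2 and Osm), the same adjusted over the list alone (median -0.75, camera adjusted p = 0.0404; adjusted p = 0.406 with an estimated correlation). Socs2 rose from 1.90 ± 1.59 (SD, n = 3) to 45.3 ± 2.80 (log2 fold change 4.13 ± 0.33 SE, adjusted p = 4.68e-05), while Socs3, another feedback inhibitor of cytokine signalling, fell from 31.6 ± 10.3 to 0.963 ± 0.103 (-4.00 ± 0.25, adjusted p = 7.7e-06). Bcl2, an anti-apoptotic gene, fell from 50.3 ± 10.1 to 20.1 ± 0.339 (-1.26 ± 0.15, adjusted p = 0.000321). Myc was at 41.1 ± 13.2 and 45.4 ± 11.03 (0.17 ± 0.27, adjusted p = 0.646), with a sign that turned without ex vivo CLP 3 (-0.12) or cCLP 2 (-0.01). Of the interferon response genes 0 of 8 rose and 7 fell, the same adjusted over the list alone (median -1.75, camera adjusted p = 2.53e-05; adjusted p = 0.330 with an estimated correlation). Of these, Oas1a was listed at 25, 18 and 32 in ex vivo CLP 1, 3 and 4 and at 0 in cCLP 2 to 4. Of the immediate early and stress genes 2 of 18 rose (Dusp2 and Egr1) and 12 fell, against 2 and 13 adjusted over the list alone (median -1.23, camera adjusted p = 0.000896; adjusted p = 0.406 with an estimated correlation). Nr4a1, an early gene of antigen receptor and stress signalling, fell from 251 ± 93.8 to 6.10 ± 1.30 (-5.10 ± 0.26, adjusted p = 3.55e-06), and Egr1 rose from 16.2 ± 4.45 to 29.7 ± 6.57 (0.85 ± 0.22, adjusted p = 0.0169). Of the unfolded protein response genes 0 of 15 rose and 12 fell, the same adjusted over the list alone (median -0.56, camera adjusted p = 0.000946; adjusted p = 0.406 with an estimated correlation), with Dnajb9 at -1.65 ± 0.12. In the integrated stress list 0 of 11 rose and 4 fell, against 0 and 3 adjusted over the list alone (median -0.26, camera adjusted p = 0.108), with Mthfd2 at -0.91 ± 0.16.

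Cholesterol synthesis was the metabolic list that rose. Of its 18 tested members 15 rose and 0 fell, against 16 and 1 adjusted over the list alone, with a median log2 fold change of 1.30 (camera adjusted p = 8.64e-08; adjusted p = 0.0982 with an estimated correlation). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), an enzyme gene of the mevalonate pathway, rose from 14.2 ± 3.81 (SD, n = 3) to 74.6 ± 4.78 (2.34 ± 0.18 SE, adjusted p = 2.96e-05). Srebf2, Pmvk and Ebp were the 3 members not called. In glycolysis 4 of 15 rose and 1 fell, the same adjusted over the list alone (median 0.069, camera adjusted p = 0.439), with the lactate transporter gene Slc16a1 at 1.62 ± 0.09 and Pgk1 at -0.52 ± 0.12. In the hypoxia response 3 of 11 rose and 3 fell, the same adjusted over the list alone, with a median of 0.007, a mean of -0.29 and camera adjusted p = 0.984. There Kdm3a was at 1.03 ± 0.11 (adjusted p = 0.000135) and Vegfa, a blood vessel growth factor gene, at -3.14 ± 0.26 (adjusted p = 4.61e-05). In oxidative phosphorylation 1 of 28 rose (Cycs, 0.93 ± 0.23) and 6 fell (Cox5a among them, -0.75 ± 0.11), against 1 and 3 adjusted over the list alone, and the median of -0.086 changed sign with the scaling (camera adjusted p = 0.239).

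Of the abundant housekeeping RNA, ribosomal protein genes differed little. Of the cytosolic ribosomal protein genes 0 of 81 tested members rose and 0 fell, also adjusted over the list alone (median 0.035, camera adjusted p = 0.645), and other scalings gave up to 8 that rose and up to 2 that fell. Of the replication-dependent histones 2 of 10 rose (Hist1h1c and Hist2h2be) and 0 fell, the same adjusted over the list alone (median 0.45, camera adjusted p = 0.231). Hist1h1c rose from 47.1 ± 16.2 (SD, n = 3) to 116 ± 17.8 (log2 fold change 1.33 ± 0.26 SE, adjusted p = 0.00483). Of the mitochondrially encoded genes 2 of 14 rose, the ribosomal RNAs mt-Rnr1 and mt-Rnr2, against 0 adjusted over the list alone, and all 14 had a positive log2 fold change (median 0.35, camera adjusted p = 0.0839). For mt-Rnr2 the log2 fold change was 0.55 ± 0.17 (adjusted p = 0.0316). Its call ended without ex vivo CLP 1 (adjusted p = 0.0803), ex vivo CLP 4 (0.0788), cCLP 2 (0.132) or cCLP 4 (0.103) and with offsets for GC content and gene length (0.0581). Mitochondrially encoded genes took 8.49% ± 0.868 of the summed values in ex vivo CLP 1, 3 and 4 and 10.8% ± 0.969 in cCLP 2 to 4, without overlap (exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow). Haemoglobin genes took 0.005% and 0.001%, and the stromal list 0.012% and 0.003% (exact permutation p = 0.1 and adjusted p = 0.233 for each). Of the 28 lists, 25 were tested as sets over these 6 libraries, with 2 called higher and 9 lower, and none of the 11 calls held with an estimated correlation. With fry all 11 kept their call and direction, among 2 lists called higher and 15 lower. However, fry tests each list by itself and not against other genes, and 43% of all genes tested were called over these 6 libraries.

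**Figure D3:**
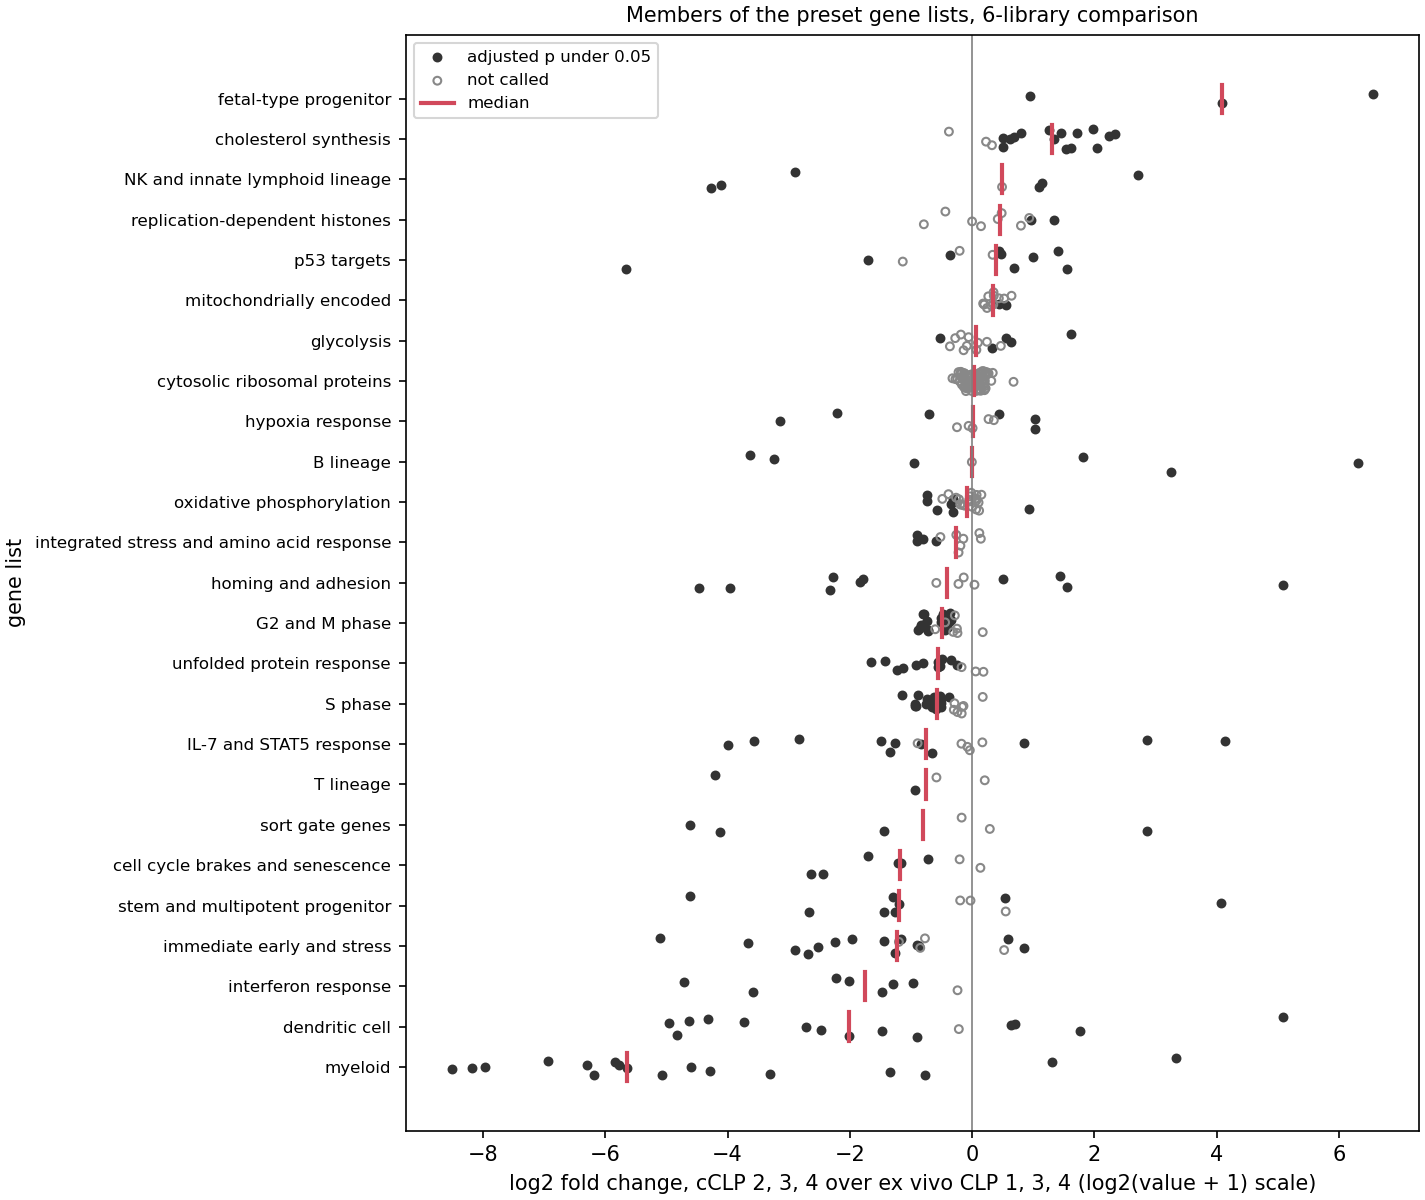
log2 fold change, cCLP 2 to 4 minus ex vivo CLP 1, 3 and 4, of each tested member (points) of the 25 lists with at least 3 tested members, with the list median in red. Cholesterol synthesis has a median of 1.30 and S phase of -0.58, and the medians of B lineage and oxidative phosphorylation change sign with the scaling. Points of genes at or near 0 in a whole group (9 listed at 0 in the myeloid list) depend on the added 1.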

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

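The position axis, the difference between the pair of doubted libraries, and the tests of exchanged labels, mixed cells, scaling and neutrophil and granule genes were chosen only after the results they test had been seen. So were the counts of splits except that of genes over the 6 libraries. The test of leaving out other pairs of libraries was fixed before its result was seen, but for a pair already picked from its profile.

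The libraries labelled ex vivo CLP replicate 2 and cCLP replicate 1 each lay with the other group. Mixed cells are argued against as the whole cause, since 100% of 33 genes high in ex vivo CLP 1, 3 and 4 and listed at 0 in cCLP 2 to 4 were at 0 in ex vivo CLP 2, and 100% of 4 genes of the opposite kind were at 0 in cCLP 1, although a small share stays open. Under the other scalings the lowest position of ex vivo CLP 2 was 1.009. The axis holds genes past a log2 limit of 2, which a library factor can hardly move, so this does not test scaling. The 0s above are deposited values, which no library factor changes. Leaving out any of the 15 other pairs of 1 library per group gave at most 0 called genes, where this pair gave 2828. Each other pair keeps ex vivo CLP 2 or cCLP 1 in the fit, so this contrast follows from how the pair was picked and decides nothing. An exchange of the labels of these libraries may account for the pattern: ex vivo CLP 2 lay at 1.009 and cCLP 1 at 0.035, and over the 2828 genes called without this pair their difference had the same direction for 95.2% (Pearson's r 0.967 across genes, which are not independent). These values restate the pattern along an axis made from the other 6 libraries, so they do not favour an exchange over a wrong label of each library on its own or a biological difference between cultures or animals, which stay open and were not tested, as no label names cultures or animals.

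Results over all 8 libraries carry this structure. A count of 0 genes is reached by every split (35 of 35, the highest other 3244), so it decides nothing about chance. Chance cannot be excluded for the 6 lists called (18 of 35 splits, highest other 14) or for the 5280 genes inside 2-fold (30 of 35 splits, highest other 5709). The 1 split with 3244 genes set ex vivo CLP 1, 3 and 4 and cCLP 1 against ex vivo CLP 2 and cCLP 2 to 4. This is the grouping by profile described above, and not that of the labels. For the 6 libraries, 10 splits are too few for a share under 0.05: 1 split gave as many as 2828 genes (highest other 0), 2 gave as many as 11 lists (highest other 11) and 5 gave as many as 5117 genes inside 2-fold (highest other 5206).

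The neutrophil genes S100a8, S100a9, Camp, Ngp and Ltf were listed above 0 in ex vivo CLP 1, 3 and 4, with S100a9 at 212, 285 and 354, and in cCLP 1 (82). They were listed at 0 in ex vivo CLP 2 and cCLP 2 to 4. A small share of mature neutrophils in ex vivo CLP 1, 3 and 4 and cCLP 1 is a candidate explanation, although the lineage-negative gate would remove them. In ex vivo CLP 1, 3 and 4, S100a8 held 35.17% to 38.9% of the sum of these neutrophil genes. S100a9 held 42.34% to 44.39%, so this sum mostly reflects S100a8 and S100a9. Each gene's share of the sum varied at most 1.7-fold between ex vivo CLP 1, 3 and 4 (Ngp, 5.91% to 10.05%). This lay inside a bound of 2-fold but outside the 1.5-fold used next, both set after the values were seen. That explanation is argued against for Ms4a3 and the primary-granule genes Mpo, Elane, Prtn3 and Ctsg. Their sum relative to the sum of the neutrophil genes above varied 3.57-fold (1.02, 2.73 and 3.64, and 7.53 in cCLP 1). Mpo was listed at 302, 744 and 1355 in ex vivo CLP 1, 3 and 4 and at 245, 284 and 339 in cCLP 2 to 4. Myeloid-primed progenitors in ex vivo CLP 1, 3 and 4 and cCLP 1 stay open and were not tested.

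In 68 of 151 groups of 4 (45%), 1 library lay far from the other 3, where chance gives about 1 in 20, or 8. The library was ex vivo CLP 2 in 26 of these and cCLP 1 in 38. Most of these genes, and the axis, were taken because they separate ex vivo CLP 1, 3 and 4 from cCLP 2 to 4, so this excess is no evidence by itself. For the genes and shares chosen before any values were seen it was 19 of 57 groups, where chance gives about 3, although genes are not independent. The library was ex vivo CLP 2 in 4 and cCLP 1 in 11. The rate of 1 in 20 does not hold for genes near 0. Pax5, Cdkn2a, Gata3, Zbtb16 and Tcf7 were listed at no more than 4 in the library that stood apart and at 0 in the others of its group. Their value of 1.0 follows from those 0s and is no evidence about the library. Values are the gap to the nearest library divided by the range of the group. In the ex vivo CLP group, ex vivo CLP 2 stood apart with 1.0 for Pax5, Cdkn2a and Igf2bp3, 0.98 for Tmem176a, 0.96 for Ly6d and Hoxa10, 0.94 for Irf8 and Slc16a1, 0.93 for Ly6a and Plk2, 0.92 for Cd74, and 0.91 for Ccl4, Oas1a and Kdm3a. It also did so with 0.89 for Lyz2, 0.88 for Cd7, 0.87 for Dnajb9, 0.86 for Pde3b and Serpinf1, 0.85 for Ifitm2, Cd79b and Nfil3, 0.84 for Eya1 and Nr4a1, and 0.83 for Ccr9. Ex vivo CLP 1 stood apart with 1.0 for Gata3 and 0.88 for the histone share, and ex vivo CLP 4 with 1.0 for Zbtb16. In the cCLP group, cCLP 1 stood apart with 1.0 for Tcf7, Gata3, Cd7, Ctsg and Oas1a, 0.97 for Bcl2, Ccr9, Eya1, Cd74, Igf2bp3 and Socs2, 0.96 for Ly6d, Mt1, Nfil3 and Socs3, 0.95 for Rag1, AB124611 and Fcgr3, and 0.94 for Il7r, Rag2, Pde3b and Sesn1. It also did so with 0.93 for Gfra1, Hoxa10 and Slc16a1, 0.92 for Kit, Tnni1 and Il18r1, 0.91 for Hmgcs1 and for the position on the axis, 0.9 for Nr4a1, 0.88 for Irf8, Lyz2 and Btg1, 0.85 for Flt3, and 0.84 for Ebf1, Ccl4 and Tmem176a. In that group cCLP 2 stood apart with 0.84 for Notch1.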

How the results depend on the processing

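The comparison of 6 libraries with all its alternatives, quantile normalization, the filter of 5, the other added values and limma without trend or robust estimation were chosen only after the results had been seen. Over the 8 libraries, genes higher and lower stayed at 0 under all alternatives except with both doubted libraries left out (1369, 1459, and 323, 481 at 2-fold; 2 lists higher, 9 lower). Genes inside 2-fold were 9558 with no filter and 8550 with the filter of 1 per 1000000, since more genes were tested. Lists higher were 2 with no filter, 2 with the replicate block, 3 with the block and GC and length offsets, 0 with an estimated correlation, 0 with fry, and 1 to 3 with 1 library left out. Lists lower were 10 with no filter, 0 with an estimated correlation, 0 with fry, and 3 to 9 with 1 library left out. Of 384 values of 16 genes, 369 kept direction and call, 11 passed the threshold in the 6 libraries, and 4 reversed: Cd27 was -0.172 in the 6 libraries and -0.073 to 0.164 with 1 library left out, Notch1 -0.007 to 0.174. Composition differences with 1 library left out were -0.292 to 0.781 points for ribosomal proteins, -0.01 to 0.01 for histones and -0.143 to 1.191 for the top 20, which was -0.117 outside mitochondrial and small RNA genes. Over the 6 libraries, genes higher, lower, 2-fold higher, 2-fold lower and inside 2-fold were 2215, 2761, 700, 1496 and 8375 with no filter and 2383, 2832, 704, 1494 and 7953 with the filter of 1 per 1000000, again as more genes were tested. Genes higher were 889 to 1584 with 1 library left out. Lists higher and lower were 0 and 0 with an estimated correlation, and lists lower 14 with no filter and 15 with fry. Of 1176 values of 62 genes, 1157 kept direction and call, 10 lost it (Spi1, Fcgr3, mt-Rnr2), 6 gained it (Flt3, Id2) and 3 reversed: Cd27 was 0.079 with GC and length offsets and Myc -0.121 to 0.35 with 1 library left out. Apart from the filters and fewer samples, the cause was not tested. DESeq2 and limma-voom were not run, as the values are not counts. With the depth unknown, no detection limit can be given for a value of 0.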

Other observations

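The MHC and Hoxa families, the granule and stromal genes and the test of stromal RNA were chosen only after values had been seen; the test of whole chromosomes was fixed beforehand.

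Most tested MHC class I genes were lower in cCLP 2 to 4 than in ex vivo CLP 1, 3 and 4. Of 12 tested genes of the class I molecules and their peptide loading, 0 rose and 11 fell, with a median log2 fold change of -1.77. H2-K1, a classical class I gene, fell from 626 ± 28.6 (SD, n = 3) to 76.8 ± 10.2 (-3.02 ± 0.12 SE), and B2m, the gene of the shared light chain, from 2715 ± 327 to 832 ± 105 (-1.71 ± 0.16). Class I genes are near copies of each other, so reads shared between them limit what a single member shows. Of 8 class II genes, 5 fell and 2 rose, the latter H2-Ob (1.05 ± 0.29) and H2-Oa (0.73 ± 0.12), which encode H2-O, a modulator of class II peptide loading. H2-Aa and H2-Ab1 were listed at 0 in cCLP 2 to 4.

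In the Hoxa cluster 3 of 4 tested genes rose. Hoxa10 is given above, Hoxa7 rose by 0.54 ± 0.13 (SE, n = 3 per group), and Hoxa9 was at 0.55 ± 0.22 (adjusted p = 0.0772). Hoxa11 was listed at 0 in ex vivo CLP 1, 3 and 4 and at 19, 19 and 25 in cCLP 2 to 4.

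RNA from OP9 stromal cells, which the sort would remove, was tested as a source of the fetal-type genes in cCLP 2 to 4. The stromal list, fixed beforehand, took 0.005%, 0.002% and 0.003% of the summed values in cCLP 2 to 4, below the 0.011%, 0.011% and 0.013% in ex vivo CLP 1, 3 and 4. Much of the ex vivo share was Serpinf1, listed at 18, 30 and 51 there and at 0, 1 and 1 in cCLP 2 to 4. The difference in share therefore decides little. Of the 30 list genes, 4, 4 and 5 were above 0 in cCLP 2 to 4, against 10, 8 and 12 in ex vivo CLP 1, 3 and 4. These low numbers argue against more than a trace of stromal RNA. Some genes of the list are also expressed in blood cells, so a trace stays open. Whether the fetal-type genes rose in the progenitors in culture or came from cells selected there stays open and was not tested.

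A gain or loss of a whole autosome shared by cCLP 2 to 4 was argued against, as the median log2 fold change of each of 19 autosomes lay within 0.087 of the median of all genes. A change in part of the cells or of part of a chromosome was not tested. Xist was listed at 42 to 103 in the 8 libraries and Tsix, its antisense gene, at 0. Over the 6 libraries Xist rose from 53.02 ± 11.65 (SD, n = 3) to 85.03 ± 6.485 (log2 fold change 0.69 ± 0.16 SE, adjusted p = 0.00954).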
